A study of Mus musculus with 2 samples.

How the data were processed

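Smad4 ChIP-seq and input DNA were sequenced from mouse forelimbs, 1 library each, on an Illumina instrument per the labels' protocols. The labels give both ages, embryonic days 12.5 and 13.5, for each library and do not say whether they were pooled before or after sequencing. The submitters' processing notes name BWA, SICER and MACS and the genome build mm9, without versions, roles or settings. BWA is an aligner, and SICER and MACS are peak callers. The file used here is 1 peak list with the columns of a MACS table, per the file headers, and the labels list 1 ChIP library for it. Only this list was analysed here. Read alignments, library sizes and coverage were not used here, so the depth of either library is unknown and the tags inside peaks (1815821 in all) are not a library total.

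The deposited columns were used as they stand. Tag counts per peak are whole numbers made by the authors' peak caller. The p score is 10 times the negative log10 of the caller's p-value, a score deposited by the authors, and 6 peaks share its highest value of 3100. The fold enrichment is named as a ratio in the column deposited by the authors, and neither its background nor whether it was transformed is stated. The FDR is a percentage deposited by the authors, at most 4.99% in the list. Peak start, end, length and summit offset are given in bp, and length equalled end minus start plus 1 for all 90984 peaks. No peak was repeated. The title of the list refers to 10 kb on either side of transcription start sites and to genes, but its columns hold neither, and whether peaks were selected on this is not known. The peak scores are the authors' and were used only to describe and rank peaks within the list.

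Genes were not assigned to peaks. The list gives no gene names, and the gene table used here is of GRCm38.p6, another assembly than mm9. None of its coordinates was used. It served only for the number of protein-coding genes on each chromosome, 21631 on the autosomes and X. Y was left out, because its peaks span only 2.72 Mb while the gene table places 256 protein-coding genes on it. Because mm9 annotation and sequence were not used here, the tests fixed before the data were examined that need genes or sequence were not run. These were the distance to transcription start sites, the number of peak-associated genes, the enrichment and peak height of the fixed gene lists (hypertrophy, immature chondrocyte, BMP and TGF-β components, Smad response, osteoblast, limb patterning, hedgehog and PTHrP, Wnt, Notch, FGF, joint, tendon, matrix remodelling, Hox, housekeeping and cell cycle genes, other cell types of the limb, and control lists of neuron, liver and olfactory receptor genes) and the motif content. No list gave a result.

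The number of peaks and the ratio of observed to expected peaks per chromosome were fixed before the data were examined. The rule for named items, which names the 10 genes with the highest p scores along with fixed genes and members of the fixed lists, was applied to peaks in place of genes and without the gene lists. Everything else (the ranking by fold, the classes of tags and length, the correlations over chromosomes, the windows) was chosen after seeing the data. Chromosome spans ran from the first peak start to the last peak end. Densities are per Mb of span, and outside dense windows per Mb of the span without those windows. Correlations used 100000 random permutations, two-sided. Shares of peaks have exact binomial (Clopper-Pearson) 95% intervals and tag counts exact Poisson 95% intervals. They cover counting error only, since peaks are loci of 1 library, not replicates, and tags without molecular identifiers are not independent molecules. Random sets of peaks or windows (10000) describe how far a median stands from others in this list. Windows of 1 Mb were assigned by peak start, and those with at least 100 peaks were described. Uniform placements (100) ignored unassembled and unmappable sequence. For each peak below the highest p score, the expected number of tags was found at which the Poisson probability of more tags equals the deposited p-value.

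The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The procedures were tested on simulated data. Expected tags were recovered within 1% for 100% of 5000 simulated peaks. Their p scores were made with the same Poisson formula. The recovery therefore checks the calculation only, not whether the deposited p-values are Poisson probabilities. Of 10 dense windows planted among 90984 uniformly placed peaks, 10 were found, with 0 others. Each planted window was given more peaks than the limit of 100, so this checks the counting only, not windows near the limit. The permutation test gave p at or under 0.05 in 6.75% of 400 sets with no relation and in 98.5% of 200 sets with a true r of about 0.7. Weaker relations, as most of those below, were not simulated, so this share does not tell how often they would be detected. Alternatives were stricter FDR and fold limits, merging of peaks less than 1 kb apart, leaving out X and Y, other windows and lengths, and all genes in place of protein-coding genes.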

Results

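The data were a single list of genomic regions that the authors' caller had called as enriched in chromatin immunoprecipitation for Smad4. Smad4 is the common partner of the receptor-activated Smad proteins and carries BMP and TGF-β signals to chromatin. ChIP-seq crosslinks proteins to DNA, pulls the fragments down with an antibody and sequences them, and regions with an excess of sequenced tags are called as peaks. The tissue was forelimb of C57BL/6 mouse embryos at embryonic days 12.5 and 13.5, ages given together for each library. There was 1 Smad4 library and 1 library of input DNA, which is chromatin sequenced without immunoprecipitation, so no comparison in this section has a replicate check. The sequencing depth of either library is unknown. The series title places the study in chondrocyte hypertrophy and the transcription factor Runx2, and the submitters looked for direct targets of Smad4 in that process. All positions are mm9, 1-based. The peaks carry no gene names, and mm9 gene annotation was not used here, so Runx2, Sox9, Id1 and the other genes chosen in advance have no values and every peak is identified by its position.

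The first question was which regions were enriched in the Smad4 library, and how strongly. The list held 90984 peaks on the 19 autosomes, X and Y, which covered 58.5 Mb and held 1815821 tags. Most were small and held few tags. The median peak was 586 bp long and held 16 tags, and 30762 peaks (33.8%, exact binomial 95% interval 33.5 to 34.1%) held exactly 15 tags, the lowest number in the list. The median deposited fold enrichment was 1.49 (quartiles 1.25 and 1.79). A fold of at least 2 was reached by 12971 peaks (14.3%), of at least 3 by 760 peaks (0.835%, 0.777 to 0.897%) and of at least 5 by 17 peaks. Below 1 lay 4013 peaks (4.41%, 4.28 to 4.55%). How the fold was calculated is not given in the sources used here and its scale is open, so weak and strong refer only to the deposited column. The intervals cover counting error only. A peak of 15 tags has an exact Poisson 95% interval of 8.40 to 24.7 tags, so differences between single peaks of this size are within counting error.

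**Figure D1:**
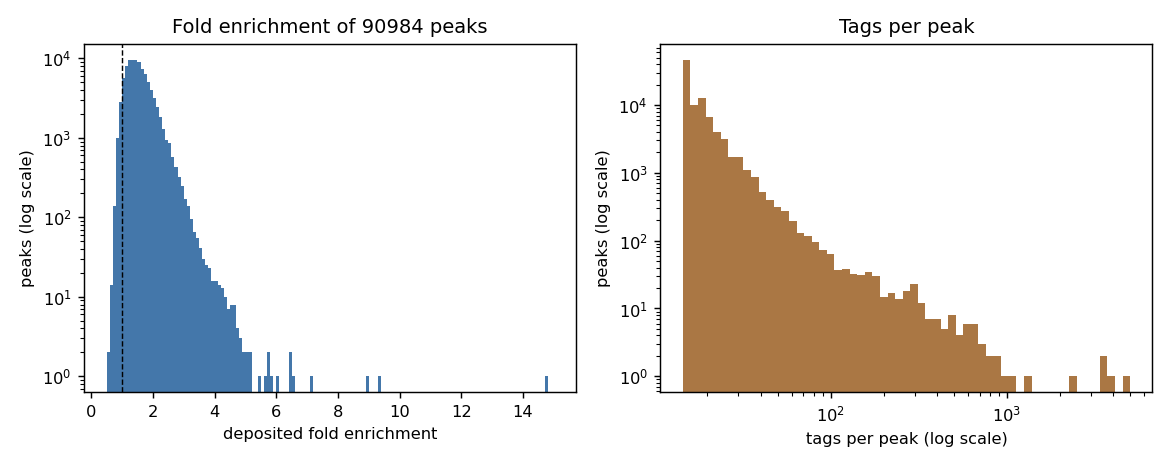
Left, number of peaks (log scale) by deposited fold enrichment in steps of 0.1, with a dashed line at 1; right, number of peaks (log scale) by tags per peak (log scale). Both fall off steeply from a mass of weak peaks, with a median fold of 1.49 and a median of 16 tags, to a single peak of 14.79-fold and a single peak of 4610 tags.

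The deposited p-values and FDR were low throughout the list. It holds only peaks that the authors' caller had called, so this follows from the selection. Within the list, 38628 peaks (42.5%) had a p score under 100. The p score, which is 10 times the negative log10 of the caller's p-value, had a median of 108 and a minimum of 50.01, a p-value of 9.98e-06. The deposited FDR had a median of 0.33% and a maximum of 4.99%. It was at most 1% for 70572 peaks (77.6%, 77.3 to 77.8%) and 0 for 89 peaks.

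The peak with the highest fold lay on chromosome 10 at 110348120 to 110348979. It held 185 tags (exact Poisson 95% interval 159 to 214 tags), with a fold of 14.79, a p score of 3100, the highest in the list and shared by 6 peaks, and an FDR of 0%. The 10 peaks with the highest p scores fell into unlike groups. In 5 of them the fold was at least 4. Besides the peak on chromosome 10, these were chromosome 2 at 57481736 to 57483094, with 460 tags and a fold of 4.09, chromosome 5 at 115121296 to 115122824, with 103 tags and a fold of 6.54, chromosome 3 at 148714976 to 148716122, with 172 tags and a fold of 4.54, and chromosome 17 at 4626017 to 4626996, with 100 tags and a fold of 6.48. In 4 others the fold was below 2, although they held 592 to 3556 tags. These were chromosome 4 at 118219328 to 118221702 with a fold of 1.75, chromosome 9 at 35112383 to 35113684 with a fold of 1.87, and chromosome 17 at 13743087 to 13746415 with a fold of 1.41 and at 39979486 to 39986190 with a fold of 0.86. The remaining peak, on chromosome 13 at 74665572 to 74668877, held 955 tags and had a fold of 2.30.

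Ranked by fold instead, a ranking added after the values were seen, the 10 leading peaks lay on 9 chromosomes and held 50 to 185 tags. Only 3 of them were also among the 10 leading peaks by p score, those on chromosomes 10 and 5 and the one on chromosome 17 at 4626017. After the peak on chromosome 10 the next highest folds were 9.37 on chromosome 17 at 56339114 to 56339660 with 63 tags (48.4 to 80.6), 8.97 on chromosome 2 at 60240300 to 60241236 with 80 tags (63.4 to 99.6) and 7.18 on chromosome 12 at 116610313 to 116611066 with 96 tags (77.8 to 117). The intervals are exact Poisson 95% intervals of the tags. An FDR of 0% was given to 9 of these 10 peaks and 0.86% to the tenth, on chromosome 9 at 19379438 to 19380470, which held 50 tags.

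The next comparison was between peaks of different size. Fold rose with the number of tags among the smaller peaks and was lower again among the larger ones. The median fold was 1.4 at 15 tags (30762 peaks), 1.5 at 16 to 20 tags (42312 peaks), 1.71 at 21 to 30 tags (12355 peaks), 1.4 at 51 to 100 tags (1030 peaks) and 1.12 above 200 tags (150 peaks). The share of peaks with a fold below 1 was 4.77% at 15 tags, 2.08% at 21 to 30 tags and 30.7% above 200 tags. The share of at least 3-fold was 0.302% at 15 tags, 1.95% at 21 to 30 tags, 4.2% above 100 and up to 200 tags and 0.667% above 200 tags. The list holds only called peaks, which bears on this comparison. If the p-values are Poisson probabilities, calling a peak of few tags takes a higher ratio of observed to expected tags than a large peak. At the lowest p score that ratio would have a median of 3.38 over peaks. How far the lower fold of large peaks follows from this limit was not tested. The 71 peaks longer than 5000 bp had a median fold of 1.11, against 1.49 in the other peaks. None of 10000 random sets of 71 peaks had a median as low, and the lowest was 1.25. Those sets drew peaks singly and matched only their number, not their tags. The long peaks lie partly in clusters, with 18 on X from 120000001 to 123000000 and 10 on chromosome 14 from 42000001 to 45000000. The range of the sets may therefore be too narrow here. These long peaks held 57.8 tags per kb at the median, against 28.8 tags per kb in the other peaks, and 21 of the 71 lay on X. Others gathered on chromosome 4 between 145356075 and 146687864, in 1 Mb windows of 59 and 61 peaks. A total of 34 peaks held at least 500 tags, and 10 of these lay on X. The largest number of tags, 4610, lay on X at 166435111 to 166447078, where the fold was 1.28. On chromosome 2, nearby peaks at 98501998 to 98504773 and at 98505845 to 98507867 held 3730 and 3661 tags, with folds of 0.99 and 0.79. Between them lay a peak at 98504882 to 98505601 with 683 tags and a fold of 1.08.

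**Figure D2:**
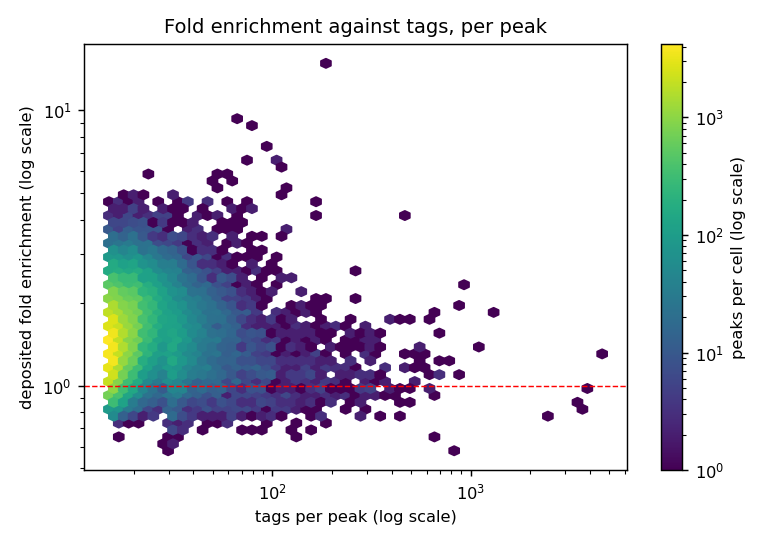
Deposited fold enrichment (log scale) against tags per peak (log scale), with color for the number of peaks in each cell (log scale) and a dashed line at a fold of 1. The peaks above 200 tags gather near the line, with a median fold of 1.12, and the peak of 14.79-fold with 185 tags stands apart.

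Peaks were then compared between chromosomes, as a check for uneven calling. Expected numbers came from the number of protein-coding genes per chromosome. Chromosome 14 had 5532 peaks, 1.55 times the number expected (exact binomial 95% interval 1.51 to 1.59), and X had 6143, 1.51 times (1.48 to 1.55). The gene-rich chromosomes had the lowest ratios, with 3574 peaks and a ratio of 0.528 (0.512 to 0.546) on chromosome 11 and 5309 peaks and a ratio of 0.622 (0.606 to 0.639) on chromosome 7. Per Mb of span, numbers of peaks differed much less, from 30.1 on chromosome 11 to 45.3 on chromosome 14. Y had 53 peaks and was left out of these comparisons.

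Over chromosomes, the densities of weak and of strong peaks were related to gene density with opposite signs. Peaks under 1.5-fold had a density of 13.6 per Mb on the gene-rich chromosome 11 and 20.1 per Mb on the gene-poor chromosome 3. Chromosome 7, the richest in genes, had 16.8 per Mb, and chromosome 12 and X, both among the poorest, had 17.8 and 17.7 per Mb, near the autosomal median of 17.5. Peaks of at least 3-fold had 0.413 per Mb on chromosome 11 and 0.128 per Mb on chromosome 3, the lowest of the autosomes. The gene-rich chromosome 19 had 0.206 per Mb, below the autosomal median of 0.279, and the gene-poor X had 0.428 per Mb. Peaks of at least 3-fold made up 1.37% of all peaks on chromosome 11 (exact binomial 95% interval 1.02 to 1.81%) and 0.351% on chromosome 3 (0.215 to 0.542%). Over 20 chromosomes, which are not independent replicates, gene density and the density of peaks under 1.5-fold had a Pearson r of -0.59 (permutation p = 0.00508, adjusted p = 0.0186) and a Spearman rho of -0.65 (permutation p = 0.00212, adjusted p = 0.00848). For peaks of at least 3-fold r was 0.47 (permutation p = 0.0346, adjusted p = 0.0462) and rho was 0.42 (permutation p = 0.065, adjusted p = 0.065). The share of peaks of at least 3-fold, which sets strong peaks against all peaks, had an r of 0.57 (permutation p = 0.00928, adjusted p = 0.0186) and a rho of 0.51 (permutation p = 0.0242, adjusted p = 0.044). All peaks together had an r of -0.43 (permutation p = 0.0587, adjusted p = 0.0587) and a rho of -0.48 (permutation p = 0.033, adjusted p = 0.044). The tests were two-sided, with Benjamini-Hochberg adjustment over these 4 relations. Without chromosomes 7 and 11, which lay farthest from the median gene density, r was -0.46 (permutation p = 0.0569) for weak peaks, 0.31 (permutation p = 0.211) for strong peaks, 0.39 (permutation p = 0.111) for the share and -0.37 (permutation p = 0.132) for all peaks, so r kept its sign, but the passing of 0.05 by weak peaks, strong peaks and the share rests on those 2 chromosomes. The r of all peaks together did not pass with all 20 chromosomes either, although their rho did. By rank, rho without them was -0.58 (permutation p = 0.0132) for weak peaks, -0.49 (permutation p = 0.0428) for all peaks, 0.31 (permutation p = 0.209) for strong peaks and 0.38 (permutation p = 0.122) for the share. With peaks in windows of at least 100 peaks left out, r for weak peaks was -0.33 (permutation p = 0.15). With all windows, r for peaks of at least 2-fold was 0.32 (permutation p = 0.164).

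**Figure D3:**
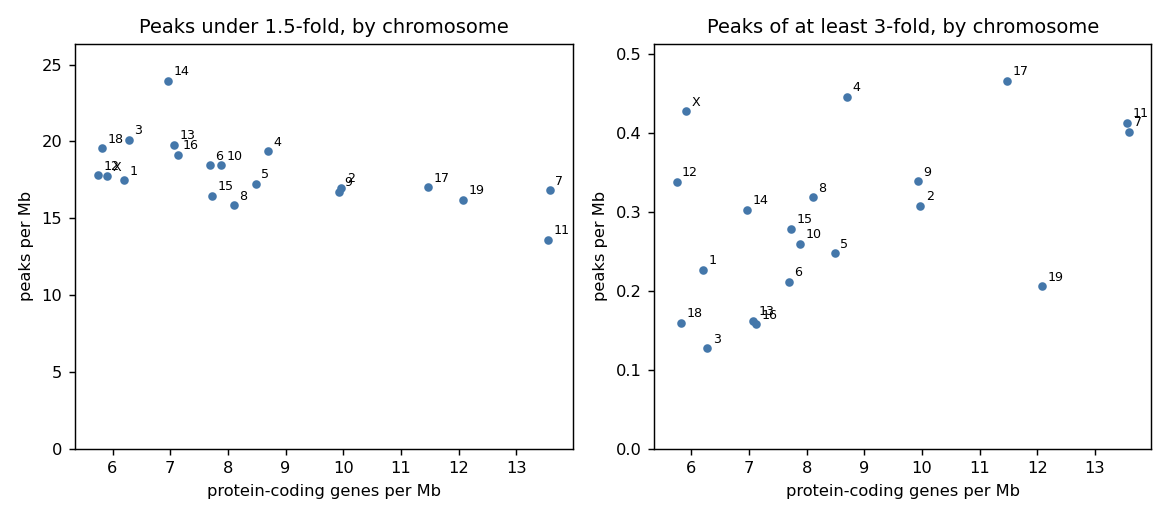
Peaks per Mb of span against protein-coding genes per Mb for the autosomes and X, for peaks under 1.5-fold (left) and of at least 3-fold (right), each point a chromosome. The density of weak peaks falls (r = -0.59) and that of strong peaks rises (r = 0.47) with gene density, with X and chromosome 19 off the course of the strong peaks.

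Peaks were also unevenly placed along chromosomes. The median distance between neighbouring peaks was 16331 bp, below the 18744 to 19131 bp seen in 100 uniform placements of as many peaks over the same spans. In windows of 1 Mb the median was 33 peaks (quartiles 27 and 40). At least 100 peaks lay in 32 of 2583 windows with a peak, and these held 5000 peaks (5.50%, exact binomial 95% interval 5.35 to 5.65%), while no window of a uniform placement passed 75. The 32 windows formed 12 regions on 6 chromosomes, with 13 windows on X and 9 on chromosome 14. On X they held 33.9% of the chromosome's peaks and on chromosome 14 27.8%.

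The largest of these regions was on chromosome 14 from 3000001 to 9000000, with 1056 peaks and a median fold of 1.45. X had 1028 peaks from 27000001 to 33000000 with a median fold of 1.38, 449 from 120000001 to 123000000 with a median fold of 1.32, and 395 from 3000001 to 5000000 with a median fold of 1.33. The single densest window, with 246 peaks, lay on chromosome 4 in the region from 60000001 to 62000000, whose 383 peaks had a median fold of 1.25 and included none of at least 3-fold. In 3 of the 12 regions the median fold was above that of peaks elsewhere, at 1.67 on chromosome 7 from 22000001 to 24000000, 1.60 on X from 51000001 to 53000000 and 1.53 on chromosome 5 from 94000001 to 96000000. Over all 12 regions the median fold was 1.38 and the median number of tags 19, against 1.49 and 16 elsewhere. Peaks of at least 3-fold made up 0.38% of peaks in the regions (exact binomial 95% interval 0.229 to 0.593%) and 0.862% elsewhere (0.801 to 0.926%), although 641 of 10000 random sets of 32 other windows had a share as low. Per Mb the same peaks were denser in the regions, at 0.594 (exact Poisson 95% interval 0.358 to 0.927) against 0.291 elsewhere (0.270 to 0.312). The regions were chosen for many peaks of any fold, and this choice itself favours a higher density. Of the 71 peaks longer than 5000 bp, 29 lay in these regions, 18 of them on X from 120000001 to 123000000.

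**Figure D4:**
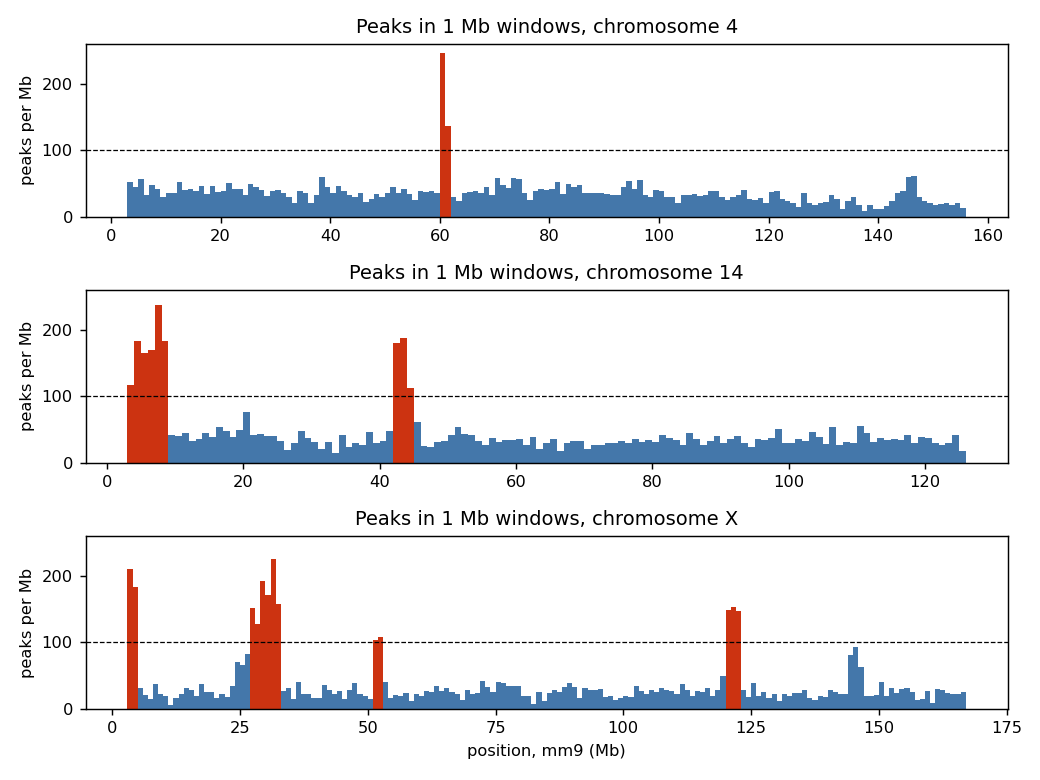
Number of peaks in each 1 Mb window along chromosomes 4, 14 and X (mm9), with a dashed line at 100 peaks and windows at or above it in red. The red windows rise to 246 peaks, against a median of 33 peaks per window over all chromosomes.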

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

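The fold limits, correlations, windows and length classes in this part were chosen after seeing the data, except the limit of 10-fold, the FDR limits on the number of peaks and on the ratios per chromosome, the merging and the sex chromosomes left out of the count. The number of peaks stayed within 1.5 times of 90984 with FDR at most 1% (70572), without X and Y (84788), with peaks less than 1 kb apart merged (82825) and with a fold of at least 1 (86971). A limit of 5% FDR left all 90984, but the highest FDR in the list is 4.99%, so this limit tests nothing. The number of peaks fell to 760 with a fold of at least 3 and to 1 with a fold of at least 10, so the fold limit decides how many regions the list holds. The ratio of observed to expected peaks on X was 1.51 and rose to 1.59 with FDR at most 1%, while those of chromosomes 14 and 11 stayed within their intervals. The correlation of peak density with gene density, -0.43 for all peaks, was 0.47 for peaks of at least 3-fold and 0.32 (permutation p = 0.164) for those of at least 2-fold, and passed 0.05 at -0.59 for those under 1.5-fold. It stayed negative and did not pass 0.05 with FDR at most 1% (-0.34), outside the dense windows (-0.23), without X (-0.41) or with all genes (-0.28). For peaks under 1.5-fold r was -0.58 with FDR at most 1% and -0.62 without X, and outside the dense windows it was -0.33 (permutation p = 0.15) with X and -0.73 without X. For peaks of at least 3-fold r was between 0.46 and 0.61 in the same settings. The share of peaks in dense windows, 5.50%, was 8.70% with at least 60 peaks, 6.16% with at least 80, 4.53% in 2 Mb windows of at least 200, 5.28% with FDR at most 1% and 3.44% without X and Y. Where the other limits do not themselves set the change, the cause was not tested. The long peaks stayed lower in fold than the others, by a difference in medians of -0.33 to -0.47. The planned results on transcription start sites, genes, gene lists and motifs, and their alternatives, were not run, because mm9 annotation and sequence were not used here. No paired analysis was possible because each group has 1 library. The depth of the libraries is unknown, and the tags of a peak limit its precision: at 15 tags the counting interval runs from 8.40 to 24.7.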

Other observations

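Of the tests in this part, the one on chance calls near the threshold was written before its result was seen, and the others after. X had 37.5 peaks per Mb over its whole span, above the autosomal median of 34.8, and 33.9% of its peaks lay in the dense windows, which were chosen for their high counts. Outside these windows it had 26.9 peaks per Mb, against a median of 34.5 on the 19 autosomes, whose lowest value was 30.1 on chromosome 11. Over whole chromosomes, peaks of at least 3-fold were not fewer on X, with 0.428 per Mb against an autosomal median of 0.279. Y had 3 peaks of at least 3-fold among its 53, the highest at 2651762 to 2652509 with 39 tags and a fold of 4.67.

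The deposited FDR may hold a count of peaks called with the libraries exchanged. If the FDR is the number of calls made with ChIP and input exchanged, divided by the number of calls at the same p score, then the percent FDR times rank, divided by 100, should be a whole number. Among the 4999 peaks with the highest p scores it was whole, within a tolerance of 0.005% FDR (its rounding) times rank, for 99.9%, against 25.8% after shuffling the FDR among these peaks. On that reading no exchanged call scored 750.02 or more, and there was 1 among the calls down to rank 100, 9 down to rank 10002, 195 down to rank 50009 and 4540 over the whole list of 90984. The last number has a rounding error of 4.55 calls.

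The first pattern to follow up is the 32 windows with at least 100 peaks. A concentration of strong binding sites is not decided by the share of peaks of at least 3-fold, 0.38%. Windows chosen for many peaks dilute that share. A number of such peaks of 19 or more was found in 133 of 10000 random sets of 32 other windows. That count does not decide either, since windows chosen for many peaks of any fold can hold more strong ones through the choice alone. This explanation stays open. Repeated or otherwise read-rich sequence would raise the tags of single peaks. The mean over windows of the median tags per peak was 21.25, above the 16.2 to 18.3 of the random sets. Those sets drew windows singly, whereas the 32 windows form 12 regions, so the range of the sets may be too narrow here. The mean of 21.25 leaves read-rich sequence as a candidate explanation for the windows as a set. The regions differed, however. In 5 of the 12, with 1890 peaks, median tags were only 16 to 18, against 16 in peaks elsewhere. The range of the random sets is for a mean over 32 windows and does not judge single regions. Copy number, mappability and input depth in these windows were not measured, and no biological explanation named by the design could be tested with 1 ChIP library.

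For the second pattern, the opposite course of weak and strong peaks with gene density, chance calls near the threshold would leave no relation at an FDR of at most 1%, but weak peaks kept an r of -0.58 there (permutation p = 0.00575, 27208 peaks). Outside the dense windows r was -0.33 over autosomes and X (permutation p = 0.15), which leaves open whether these windows are the source for weak peaks. Strong peaks kept an r of 0.48 there (permutation p = 0.0336). Of the 757 strong peaks on these chromosomes 738 lay outside the windows, so leaving the windows out could change r little. That the windows hold so few strong peaks argues against them as the source for strong peaks. On the autosomes alone r for weak peaks outside the windows was -0.73 (permutation p = 0.00019), which argues against the windows there, but the test was narrowed to autosomes only after the value with X had been seen. A bias of sequencing or calling with base composition and a true difference between weak and strong Smad4 sites remain open and were not tested. Without chromosomes 7 and 11, r was 0.31 (permutation p = 0.211) for strong peaks and -0.46 (permutation p = 0.0569) for weak peaks, whose rho was -0.58 (permutation p = 0.0132).

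The third pattern is the 4013 peaks with a fold below 1 and a p-value under the calling limit. If they are Poisson probabilities, the deposited p-values need a median of 2.23 expected tags per peak, a ratio of observed to expected tags of 7.81 at the median, while the deposited fold has a median of 1.49. The ratio was 3.92 at the median for peaks with a fold below 1 and 42.1 for those of at least 3-fold. Only 0.0583% of 90978 peaks had a fold within 1.5 times of that ratio, but their tags and the lowest p score alone put the ratio over that bound for 84.8%, so this share decides nothing. The 2 measures rose together over peaks (Spearman rho 0.80, peaks not being independent replicates). If the p-values are such probabilities, the ratio behind them is above 1 for every called peak. The 4013 folds below 1 therefore argue against the fold being that ratio as it stands. A rising transformation of this same ratio would give a rho near 1, which the 0.80 argues against. The ratio was calculated here from the tags and the p score, and the fold may rest on other counts or another background. The 0.80 therefore does not tell whether the fold was transformed. What the fold column rests on was not settled.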
